A study of Arabidopsis thaliana with 10 samples.

How the data were processed

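Poly(A) RNA of whole Arabidopsis seedlings was sequenced after a TruSeq Stranded mRNA preparation, per the labels. The 10 libraries fell into 5 groups of 2: Col-0 mock, Col-0 rapamycin, RiD mock, RiD rapamycin and RiD brassinolide. Groups and replicate numbers were taken from the sample labels, and 0 columns of the deposited table were left without a sample. The signal values are normalized counts per transcript, as deposited by the authors. Per the submitters' processing notes Salmon and DESeq2 were used, and versions, settings, genome build, annotation and the role of the strand in counting are not given in the sources used here. The median over transcripts of the ratio to the geometric mean was 0.0107 on the log2 scale in each of the 10 columns, which is the form that median-ratio size factors give. How far reads of similar gene copies were shared out is likewise not known.

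The table held 40812 transcripts of 32753 loci, of which 5880 had more than 1 transcript. Values were summed per locus. Symbols came from the TAIR10.1 reference table, and 705 loci were not in it. Transcript lengths and GC content came from the exon coordinates and genome sequence of TAIR10.1. The reference was used for nothing else.

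In each column the low values lay near whole multiples of a step, read as the value of 1 read. With a tolerance of 0.1 reads and values up to 20.5 reads, 8 of 10 columns had at least 95% of low values at whole multiples, while Col-0 mock 1 had 51.7% and Col-0 rapamycin 2 86.7%. Totals divided by the step gave 18.4 to 19.9 M reads for libraries numbered 1 and 29.2 to 33.9 M for those numbered 2. Organelle transcripts made up 0.02 to 0.38% of a library and the 10 most abundant loci 4.6 to 7.2%. A fold against a group whose libraries were all at 0 was set against a floor of 3 reads per library, averaged over the group.

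The groups, comparisons, gene lists, tests, naming rule and most alternatives were fixed before the data were examined. That plan took raw counts as the first case and normalized values as the second, and the second was used. Sums were transformed as log2 of the value plus 1, so that changes of loci near 0 depend on that constant. The 23285 loci with at least 1 normalized count in at least 2 libraries were tested by limma 3.58.1 with a mean-variance trend and robust moderation. The model held the 5 groups alone, over all 10 libraries, with 5 residual degrees of freedom. Loci with an adjusted p under 0.05 (Benjamini-Hochberg, within a comparison) are called. The comparisons were rapamycin against mock in RiD and in Col-0, the difference between these effects, brassinolide against mock in RiD, rapamycin against brassinolide in RiD, and RiD mock against Col-0 mock. Whether the 2 libraries of a group came from separate plantings is not given in the sources used here, so p-values measure the spread between these libraries.

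Libraries with the same number deviated together. Deviations from the group means correlated at 0.32 to 0.51 in all 10 pairs of groups, and at 0.69 to 0.90 among loci above the median mean. The labels do not say what the number stands for. It was treated as a batch visible in the values, decided before calls were compared, and a fit with the number as a block, with 4 residual degrees of freedom, is given beside the fit without it. Comparisons that share mock libraries share their chance values, and the correlation of the rapamycin and brassinolide responses was therefore set against 50 simulated draws of unchanged groups. The fits were tested on simulated counts of RiD rapamycin against RiD mock, in 5 draws with 200 changed loci each, all with a mean of at least 20. The counts were drawn with an assumed dispersion and not with the spread measured in these libraries. Every group was given the same shift between the numbers, as the block fit assumes, so the setting favoured the block. Without the block 0%, 4.8%, 74.4% and 96% of loci changed 1.5-fold, 2-fold, 4-fold and 8-fold were called, and 34.8%, 82.8%, 99.6% and 100% with it. False calls made up 0% without and 4.6% with the block.

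The 26 lists, written from general knowledge, held 383 members at 381 loci, all in the table. They covered BR biosynthesis, BR inactivation, BR signalling components, BR-responsive growth regulators, SAUR genes, Aux/IAA and GH3 genes, expansins, xyloglucan endotransglucosylases, primary wall cellulose synthesis, gibberellin metabolism and signalling, and dark growth and light signalling regulators. Others were nuclear photosynthesis genes, chlorophyll synthesis, flavonoid and anthocyanin synthesis, immune response genes, abscisic acid and drought response, xenobiotic response, cytosolic ribosome and nucleolus, autophagy, dark and sugar starvation, and cell division. The last were markers of root hair and root epidermis, root endodermis and stele, xylem and secondary wall, the stomatal lineage, and seed storage and embryo remnants. Lists were tested by camera of limma with a preset correlation of 0.01, adjusted over the 26 lists, and also with an estimated correlation. Members were also adjusted over the list alone.

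Genes were named by a rule. It took BRI1 and BAK1, up to 4 tested members of each list with the smallest adjusted p, and the 6 largest increases and 6 largest decreases among called loci with a mean of at least 5 and no overlap between groups. For the difference of effects every pair of RiD libraries had to have the same sign, and for rapamycin against brassinolide any called list member qualified. Loci without a symbol are given by identifier.

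Alternatives were another pseudocount, filter, scaling (TMM or quantile), threshold or list test, limma without a trend, only the libraries compared, the block, and each library left out in turn. Where a group kept 1 library, that library was assumed to vary like the other groups. Without the block, such a group held 1 number alone, so part of the shift between the numbers entered its comparisons. Chosen after seeing the data were edgeR 4.0.16 on reads recovered from the 6 RiD libraries (quasi-likelihood, TMM, filterByExpr, 20276 loci), transcripts not summed, and the block fit with each library left out. Groups of 2 allowed no count over other splits of the libraries. Other software was R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.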

Results

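RNA abundance was measured by sequencing in 10 libraries from whole seedlings of Arabidopsis thaliana, kept for 5 days in the dark on medium with 2 µM of a compound given in the labels as PPZ. The seedlings were of the wild-type accession Col-0 or of a line called RiD-BRI1/BAK1, here RiD, which is named after the brassinosteroid receptor kinase BRI1 and its co-receptor kinase BAK1. Col-0 seedlings had a mock treatment or 100 nM rapamycin, a bacterial macrolide that brings the FKBP protein and the FRB domain of the TOR kinase together. RiD seedlings had a mock treatment, 100 nM rapamycin or 100 nM brassinolide, the most active brassinosteroid hormone of plants. Each of the 5 groups held 2 libraries, numbered 1 and 2 in the labels. By the series title and design, the question was whether a chemical can switch on a plant membrane receptor kinase. The comparisons therefore asked what rapamycin changed in RiD and in Col-0, how this resembled the response to brassinolide, and how the lines differed.

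The values were normalized counts, given below as mean ± SD of the 2 libraries of a group. Each library summed to 23244655 to 26987555 normalized counts. From the size of 1 read in each column, libraries numbered 1 were estimated to hold 18.4 to 19.9 M reads and those numbered 2 to hold 29.2 to 33.9 M, so that 3 reads corresponded to 2.19 to 4.18 normalized counts. Between 22026 and 22767 loci had a value above 0 in a library, and 23285 were tested. Replicate libraries correlated across loci at r = 0.976 to 0.982 on the log2 scale. The first principal component held 55.0% of the variance. RiD rapamycin libraries scored 113.6 and 117.3 on it, RiD brassinolide libraries 62.0 and 50.9, and the other 6 libraries -61.8 to -47.3. The second component, with 14.9%, separated the libraries by number: those numbered 1 scored -48.0 to -33.1 and those numbered 2 scored 22.0 to 54.1. The count of called loci of each comparison is therefore given also from a fit with the number as a block, and counts of list members where the block moved them by over 1.5 times.

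**Figure D1:**
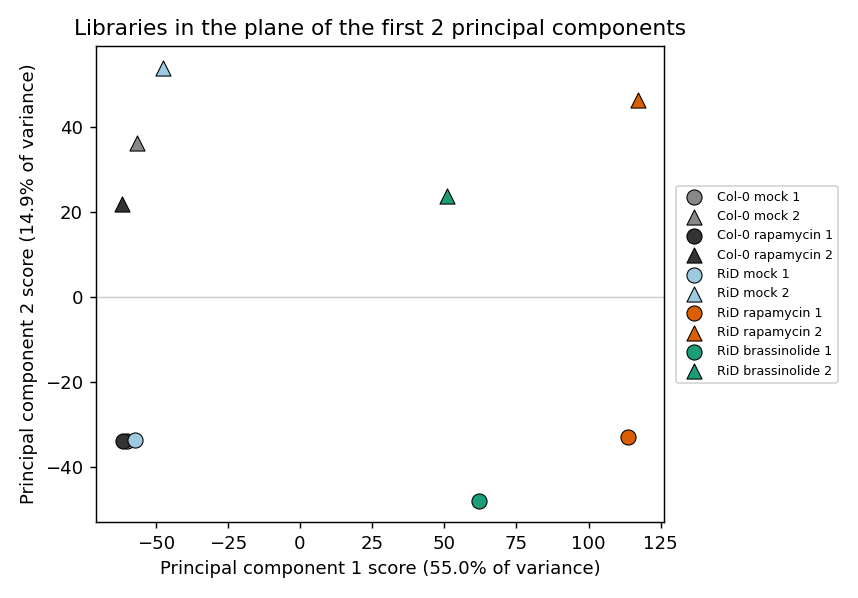
Scores of the 10 libraries on the first 2 principal components of the log2 normalized counts, with each axis giving its share of the variance; colour marks the group, circles the libraries numbered 1 and triangles those numbered 2. RiD rapamycin scored 113.6 and 117.3 on component 1, RiD brassinolide 62.0 and 50.9, and the 6 other libraries -61.8 to -47.3.

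The genes after which the RiD line is named had higher values in it. BAK1 (AT4G33430) averaged 2002 ± 146 normalized counts in Col-0 mock and 1997 ± 34.7 in Col-0 rapamycin, against 5012 ± 146 in RiD mock, 5894 ± 122 in RiD rapamycin and 5304 ± 183 in RiD brassinolide. BRI1 (AT4G39400) averaged 4523 ± 1559 and 4273 ± 439 in the Col-0 groups, against 10358 ± 2614, 8751 ± 2304 and 8547 ± 1519 in the RiD groups. For each gene all 6 RiD libraries lay above all 4 Col-0 libraries. In RiD mock against Col-0 mock the log2 difference was 1.33 (SE 0.13) for BAK1, with an adjusted p of 0.102, and 1.22 (SE 0.30) for BRI1, with an adjusted p of 1, so that neither passed the threshold. With the number as a block the adjusted p was 2.32e-06 for BAK1 and 6.2e-05 for BRI1, the lowest over the alternatives tried, where the highest was 1 for each gene. Whether an introduced sequence contributed to these values is not given in the sources used here. Within RiD, rapamycin against mock gave 0.23 for BAK1 (adjusted p = 0.252, with the block 0.0337) and -0.25 for BRI1 (adjusted p = 0.626), and brassinolide against mock gave 0.08 and -0.27.

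In RiD, rapamycin lowered the transcripts of 6 of 10 genes of the BR biosynthesis list and raised those of all 20 SAUR genes. DWF4 (AT3G50660), the hydroxylase of an early rate-limiting step of brassinosteroid synthesis, fell from 2903 ± 0.215 to 24.5 ± 3.19 normalized counts, a log2 change of -6.84 (SE 0.16, adjusted p = 7.11e-07). CPD (AT5G05690), a cytochrome P450 of the same pathway, fell from 17039 ± 1794 to 1198 ± 89.0, which is 14.2-fold lower (adjusted p = 1.64e-05). BAS1 (AT2G26710), a P450 that inactivates brassinosteroids, rose from 267 ± 77.9 to 2282 ± 540.3, 8.59-fold (adjusted p = 0.000196). SAUR9 (AT4G36110), one of the small auxin-up RNA genes tied to cell expansion, rose from 28.6 ± 0.272 to 1647 ± 132, 55.7-fold (adjusted p = 1.38e-05). In all, 5120 loci were called in RiD rapamycin against RiD mock, 2857 higher and 2263 lower, of which 3486 changed at least 2-fold.

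The BR biosynthesis list had 6 of 10 tested members lower and 0 higher, 6 lower also when adjusted over the list alone and 7 with the block, with a median log2 change of -2.78. Its test gave an adjusted p of 7e-07, and 0.065 with an estimated correlation. Besides DWF4 and CPD, BR6OX2 (AT3G30180), the oxidase that forms brassinolide, fell from 7464 ± 651 to 22.0 ± 6.25 and BR6OX1 (AT5G38970) from 395 ± 3.15 to 1.46 ± 0.0979. In BR inactivation 2 of 6 rose and 1 fell (adjusted over the list alone 4 and 1), with a median of 0.97 and an adjusted p of 0.159. SOB7 (AT1G17060), a P450 related to BAS1, rose from 766 ± 39.5 to 2228 ± 152, and PIZ (AT4G31910), an acyltransferase, fell from 416 ± 12.2 to 86.3 ± 21.5. Of 20 BR signalling components 3 rose and 4 fell (adjusted over the list alone 3 and 5, with the block 12 and 5), with a median of 0.37 and an adjusted p of 0.536. BEH2 (AT4G36780), of the BZR1 transcription factor family, fell by 3.37 on the log2 scale, from 5689 ± 825 to 549 ± 84.2. The receptor homologue BRL3 fell from 317 ± 64.4 to 106 ± 19.4 and the co-receptor homologue BKK1 rose 2.25-fold to 905 ± 5.9. Of 16 BR-responsive growth regulators 6 rose and 4 fell (adjusted over the list alone 7 and 5), and the median of 0.33 differed in sign from the mean of -0.13 (adjusted p = 0.371). BEE1 (AT1G18400), a basic helix-loop-helix factor induced by brassinosteroid, rose 4.52-fold and PRE6 (AT1G26945) 3.85-fold, while PRE3 (AT1G74500) fell by 5.62 on the log2 scale, to 1.08 ± 0.442.

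All 20 SAUR genes rose, with and without the block and also when adjusted over the list alone, with a median of 2.98 (adjusted p = 1.06e-13, and 0.24 with an estimated correlation). SAUR16 (AT4G38860) rose from 49.5 ± 19.3 to 648 ± 30.1, SAUR62 from 30.9 ± 1.92 to 299.6 ± 16.4, and SAUR10 from 6.23 ± 2.12 to 367 ± 85.7. Of 16 Aux/IAA and GH3 genes 6 rose and 3 fell (adjusted over the list alone 8 and 3), with a median of 0.82. Their test gave an adjusted p of 0.0402, which was 0.37 with an estimated correlation, 0.102 without RiD mock 2 and 0.0685 without RiD rapamycin 1. GH3.2 (AT4G37390), which conjugates auxin, rose 6.81-fold and the auxin-response repressor IAA19 rose 4.01-fold, while IAA29 fell 4.61-fold from 468 ± 26.2. Of 17 xyloglucan endotransglucosylases, which remodel cell walls, 8 rose and 4 fell (adjusted over the list alone 9 and 4), with a median of 0.89 (adjusted p = 0.00912, and 0.311 with an estimated correlation). XTH23 rose 4.82-fold and XTH18 3.75-fold. The expansins, wall-loosening proteins, went both ways: 6 of 17 rose and 5 fell (adjusted over the list alone 6 and 8, with the block 6 and 8), with a median of -0.22 and an adjusted p of 0.451. EXPA8 rose from 878 ± 113 to 2954 ± 489, and EXPA5 (AT3G29030) fell from 428 ± 43.7 to 27.4 ± 1.32, 15.1-fold. Among 15 genes of gibberellin metabolism and signalling 5 rose and 2 fell, the same counts adjusted over the list alone (with the block 6 and 4), with a median of 0.21 and an adjusted p of 0.208. GA2OX8 (AT4G21200), a gibberellin-inactivating oxidase, rose from 2.49 ± 0.128 to 443 ± 26.1, and GA20OX1, a synthesis gene, from 20.8 ± 5.67 to 177 ± 84.5.

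Some genes of the ribosome, chlorophyll, photosynthesis and cell division lists fell with rapamycin in RiD, and some of the starvation and autophagy lists rose. The tests of these 6 lists passed with the preset correlation and none with an estimated correlation. In the cytosolic ribosome and nucleolus list 12 of 25 fell and 0 rose (adjusted over the list alone 15, with the block 24), with a median of -0.80 (adjusted p = 2.27e-07, and 0.37 with an estimated correlation). FIB2 (AT4G25630), a nucleolar fibrillarin, fell from 511 ± 73.1 to 102 ± 35.4, and RPL5A from 9088 ± 289 to 4333 ± 297. Of 11 chlorophyll synthesis genes 6 fell (adjusted over the list alone 8, with the block 10), with a median of -0.78 (adjusted p = 0.000378, and 0.125 with an estimated correlation). PORA, which reduces protochlorophyllide in the light, fell from 50206 ± 4598 to 21064 ± 4314. Of 31 nuclear photosynthesis genes 5 fell (adjusted over the list alone 11, with the block 24, and 1 rose with the block), with a median of -0.60 (adjusted p = 0.000184, and 0.548 with an estimated correlation). The light-harvesting gene LHCB1.2 fell from 3096 ± 956 to 684 ± 224. In cell division 8 of 21 fell and 3 rose (adjusted over the list alone 10 and 3, with the block 12 and 3), with a median of -0.75 (adjusted p = 0.0109, and 0.198 with an estimated correlation). The cyclin CYCD3;3 fell from 347 ± 85.8, by 1.88 on the log2 scale, and the replication licensing factor MCM4 (AT2G16440) from 207 ± 17.4, by 1.03.

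Of 10 genes of dark and sugar starvation 7 rose (adjusted over the list alone 7, with the block 10), with a median of 1.07 (adjusted p = 1.5e-05, and 0.125 with an estimated correlation). DIN2 (AT3G60140), a beta-glucosidase gene induced in the dark, rose from 6952 ± 317 to 70468 ± 2993, 10.1-fold. In autophagy 4 of 23 rose (adjusted over the list alone 9, with the block 19, and 1 fell with the block), with a median of 0.55 (adjusted p = 0.000391, and 0.24 with an estimated correlation), among them ATG8E from 3699 ± 108 to 6255 ± 359. Of 20 immune response genes 10 rose and 2 fell (adjusted over the list alone 10 and 4, with the block 11 and 4), with a median of 0.67 (adjusted p = 0.0155, and 0.228 with an estimated correlation). WRKY70 rose from 136 ± 23.4 to 1046 ± 18.1 and WRKY53 from 10.5 ± 3.47 to 117 ± 10.2, while PAD3, of camalexin synthesis, fell from 67.1 ± 3.61 to 5.84 ± 0.391. Counts of called members moved when 1 library was left out, which also left the numbers unequal between the groups. Without RiD mock 1 they were 5 for ribosome, 2 for chlorophyll, 2 for photosynthesis, 1 for autophagy and 4 for cell division. Without RiD rapamycin 2 they were 5, 2, 2, 2 and 5. Without RiD rapamycin 1 photosynthesis had 10, autophagy 2 and cell division 3, and without RiD mock 2 cell division had 4.

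Some markers of particular cell types were called with rapamycin in RiD as well, while of their 5 lists that of seed remnants alone passed its test. Of 10 root hair and root epidermis markers 6 fell and 2 rose (adjusted over the list alone 6 and 3), with a median of -3.39. Their test gave an adjusted p of 0.0598, which was 0.32 with an estimated correlation, 0.0376 without RiD rapamycin 2, 0.0476 without RiD brassinolide 1 and 0.0479 without RiD brassinolide 2. RHD6, a root hair regulator, fell from 31.3 ± 7.77 to 2.16 ± 0.886, and NRT2.1, a root nitrate transporter, rose from 0 to 280.4 ± 123, at least 89.4-fold over the floor of 3 reads per library. Among 6 root endodermis and stele markers 3 rose (adjusted over the list alone 3, and 1 fell, the same with the block), with a median of 0.62. Their test gave an adjusted p of 0.0538, which was 0.275 with an estimated correlation, 0.0393 without RiD mock 1 and 0.036 without RiD rapamycin 1. GPAT5, of suberin synthesis, rose from 2.74 ± 1.61 to 243 ± 22.9 and CASP1, of the Casparian strip, from 1215 ± 255 to 4511 ± 94.0. Of 12 seed storage and embryo remnants 2 rose (adjusted over the list alone 1, with the block 1), with a median of 1.95. The adjusted p was 0.0402, which was 0.548 with an estimated correlation, 0.0751 with the block, 0.371 without RiD mock 1 and 0.0872 without RiD rapamycin 1. This count was 1 without any Col-0 library or RiD rapamycin 1, 0 without RiD mock 1 or RiD rapamycin 2 and 5 without RiD mock 2. Of 9 stomatal lineage markers 1 rose and 1 fell (adjusted over the list alone 1 and 1, with the block 2 and 2), with a median of 0.10 and an adjusted p of 0.768. TMM, a stomatal patterning receptor, rose from 113 ± 7.1 to 379 ± 11.2. Of 8 xylem and secondary wall markers 0 were called by limma (with the block 1 lower), with a median of -0.09 and an adjusted p of 0.536.

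The remaining lists were not called in RiD rapamycin against RiD mock. Primary wall cellulose synthesis had 1 of 8 higher (adjusted over the list alone 2 higher and 1 lower, with the block 6 and 1), with a median of 0.32 and an adjusted p of 0.225. Dark growth and light signalling regulators had 1 of 16 higher and 2 lower (adjusted over the list alone 1 and 2, with the block 4 and 7), with a median of -0.23 and an adjusted p of 0.451. The early light-induced gene ELIP2 fell from 327 ± 226 to 26.0 ± 6.49. Flavonoid and anthocyanin synthesis had 2 of 9 lower (adjusted over the list alone 2, with the block 4, and 1 higher with the block), with a median of -0.53 and an adjusted p of 0.188. Abscisic acid and drought response had 2 of 12 higher and 1 lower (adjusted over the list alone 2 and 1, with the block 6 and 3), with a median of 0.47, or 0.37 with genes at 0 set to the floor, and an adjusted p of 0.326, and KIN1 fell from 39.8 ± 3.42 to 6.97 ± 2.01. Xenobiotic response had 3 of 10 higher and 2 lower (adjusted over the list alone 3 and 3, with the block 5 and 3), with a median of 0.24 opposite in sign to its mean of -0.20 and an adjusted p of 0.831. The glucosyltransferase UGT73B4 fell from 1700.3 ± 196 to 236 ± 33.6. Without RiD mock 1, RiD mock 2, RiD rapamycin 1 or RiD rapamycin 2, 1 gene was called of dark growth and 0 or 1 of flavonoid. The calls of cellulose and stomatal genes fell to 0 and 1 without 3 of these 4 libraries, all but RiD rapamycin 2 and all but RiD mock 1 respectively. Abscisic acid had 1 called without RiD mock 2 or RiD rapamycin 1, xenobiotic response 3 without RiD mock 2, and flavonoid 0 or 1 also without any Col-0 or RiD brassinolide library.

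Outside the lists, CYP78A10 (AT1G74110) rose from 0.401 ± 0.566 to 1291 ± 200.5, and the blue copper protein gene BCB (AT5G20230) rose 336-fold to 11526 ± 1779.8. AT5G57785 fell from 765 ± 179.6 to 0 and CYP82F1 from 235 ± 15.0 to 0, at least 236-fold and 72.5-fold lower against the floor of 3 reads per library. ACS11 (AT4G08040), of ethylene synthesis, fell from 523 ± 114 to 0.695 ± 0.984. The loci given with a rise or fall in RiD rapamycin against RiD mock were only part of those called under the naming rule. Those given were called in each of the 10 fits that left out 1 library, while other loci of the rule lost the call in some. The count of 5120 was 3018 without RiD mock 1, 3398 without RiD rapamycin 1 and 2945 without RiD rapamycin 2, and with the block it was 11215, which held 5100 of the 5120.

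**Figure D2:**
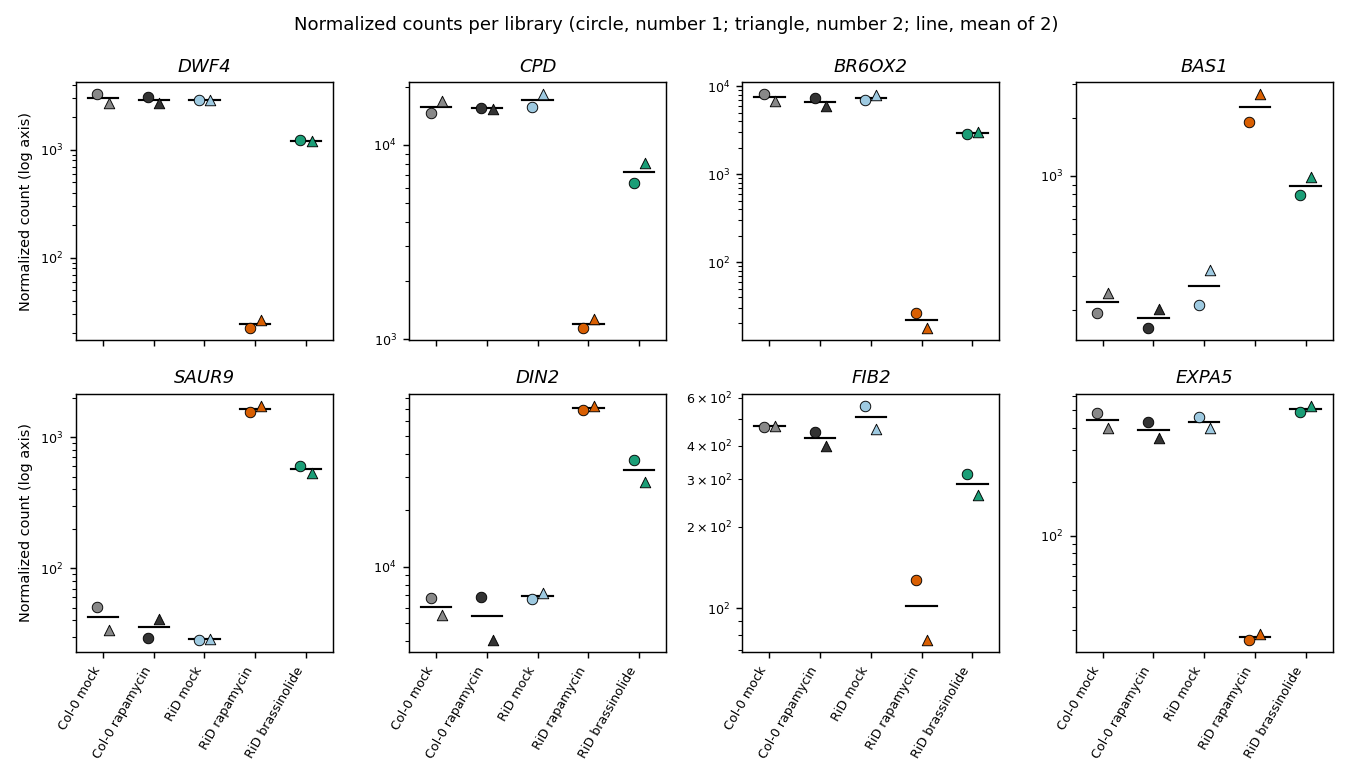
Normalized counts of 8 genes per library on a log axis in the 5 groups, with circles for libraries numbered 1, triangles for those numbered 2 and a line at the mean of the 2. DWF4 averaged 2903 in RiD mock, 24.5 in RiD rapamycin and 1219 in RiD brassinolide, and 2999 and 2900.4 in Col-0 mock and Col-0 rapamycin.

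In wild-type Col-0, no locus was called between rapamycin and mock. DWF4 averaged 2999 ± 416 normalized counts in Col-0 mock and 2900.4 ± 226 in Col-0 rapamycin, CPD 15715 ± 1661 and 15435 ± 39.1, and BR6OX2 7499 ± 986 and 6719 ± 961. SAUR9 averaged 42.1 ± 11.9 and 35.4 ± 8.26, and DIN2 6109.6 ± 902 and 5467 ± 2000.4. By limma the count was 0 at an adjusted p under 0.05, with a lowest adjusted p of 0.279 and 557 loci at an unadjusted p under 0.05. It was 1 without RiD mock 1 or RiD mock 2. With the block 43 loci were called, 5 higher and 38 lower, and this count was 5 without Col-0 mock 1, 10 without Col-0 mock 2, 405 without Col-0 rapamycin 1, and 27 without RiD mock 2 or RiD brassinolide 1.

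In Col-0, 6 lists were called by camera, all lower with rapamycin, although no member of any list was called. Of these, the SAUR, Aux/IAA and GH3, expansin and gibberellin lists were called lower also in RiD mock against the same Col-0 mock libraries. For these lists an effect of rapamycin in Col-0 cannot be told apart from high values of the Col-0 mock libraries. The xylem and secondary wall markers had a median of -0.84 (adjusted p = 1.9e-08, and 0.287 with an estimated correlation), with 2 of 8 lower when adjusted over the list alone and 2 with the block. The protease genes XCP1 (AT4G35350) averaged 789 in Col-0 mock and 396 in Col-0 rapamycin, a log2 difference of -1.01 (adjusted p = 1, with the block 0.0479), and XCP2 1061 and 605 (adjusted p = 1, with the block 0.0167). SAUR genes had a median of -0.57 (adjusted p = 1.61e-08, and 0.475 with an estimated correlation), which was 0.426 without Col-0 rapamycin 1. Xenobiotic response had a median of -0.41 (adjusted p = 2.49e-06, and 0.475 with an estimated correlation), which was 0.164 without Col-0 rapamycin 2. With the block 1 of 10 was lower, GSTU24, and 9 when adjusted over the list alone. The expansins had a median of -0.16 (adjusted p = 0.00258, and 0.438 with an estimated correlation), which was 0.148 without Col-0 rapamycin 2, and EXPA2 averaged 214 ± 41.4 and 45.4 ± 9.91 (adjusted p = 0.876, with the block 0.0253). Aux/IAA and GH3 genes had a median of -0.15 (adjusted p = 0.00812, and 0.475 with an estimated correlation; 0.406 without Col-0 mock 1 and 0.164 without Col-0 rapamycin 2). Gibberellin metabolism and signalling had a median of -0.11 (adjusted p = 0.00935, and 0.287 with an estimated correlation), which was 0.11 without Col-0 mock 2, 0.0779 without Col-0 rapamycin 1 and 0.076 without Col-0 rapamycin 2. Without Col-0 mock 1 the lists of cellulose, cell division and root endodermis passed as lower and those of photosynthesis and ribosome as higher. Without Col-0 rapamycin 2 that of abscisic acid passed as higher. The directions of the cellulose, photosynthesis, ribosome and abscisic acid lists turned without Col-0 mock 2. The last 2 turned also without Col-0 rapamycin 1. These fits held no block, so a left-out library set unequal numbers against each other. The median shift of number 2 against number 1 was -0.37 for ribosome, -0.32 for photosynthesis and 0.35 for cellulose genes. The changes of these lists between fits therefore cannot be told apart from the shift between the numbers. Adjusted over the list alone 1 expansin and 1 immune response gene were lower, the latter ICS1, with 248 in Col-0 mock and 113 in Col-0 rapamycin (adjusted p = 0.802, with the block 0.0117).

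The effect of rapamycin itself differed between the lines at many loci. The test of the difference called 2341 loci, 1512 with a more positive and 829 with a more negative change in RiD than in Col-0. The log2 effect in RiD minus that in Col-0 was -6.79 (SE 0.23, adjusted p = 8.95e-06) for DWF4, -3.80 (SE 0.24, adjusted p = 0.00024) for CPD and -8.21 (SE 0.30, adjusted p = 1.7e-05) for BR6OX2. It was 3.37 (SE 0.38, adjusted p = 0.00172) for BAS1, 6.04 (SE 0.35, adjusted p = 0.000158) for SAUR9, 3.54 (SE 0.37, adjusted p = 0.0012) for DIN2 and -2.20 (SE 0.35, adjusted p = 0.0069) for FIB2. The same 7 genes and those in the next sentence were called in every fit that left out 1 library, while other called loci of the naming rule lost the call in some. Further genes with a larger positive effect in RiD were BEE1 with 2.32, EXPA8 with 2.07, IAA6 with 4.66, GA2OX8 with 7.02, WRKY70 with 3.06, WRKY53 with 3.68, GPAT5 with 6.79, CASP1 with 1.99 and XTH23 with 2.27, and EXPA5 (-3.73), BEH2 (-3.50) and IAA29 (-1.96) had a negative one. PELPK1 (AT5G09530) averaged 224 ± 23.9 in Col-0 mock, 36.6 ± 3.45 in Col-0 rapamycin, 34.2 ± 15.5 in RiD mock and 3965 ± 81.2 in RiD rapamycin, a difference of 9.47 in the effects. The transcription factor gene MYB55 (AT4G01680) averaged 1508 ± 391, 1552 ± 353, 1225 ± 193 and 4.76 ± 0.833, a difference of -7.78.

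For 14 lists the effects differed between the lines by camera. Each difference includes the change in Col-0, which by camera was lower for the SAUR, Aux/IAA and GH3 and gibberellin lists. BR biosynthesis had a median difference of -2.69 with 6 of 10 lower (adjusted over the list alone 6; adjusted p = 4.47e-08), and it held with an estimated correlation (adjusted p = 0.0423), though not with the block as well (0.121). SAUR genes had a median of 3.68 with 18 of 20 higher (adjusted over the list alone 20; adjusted p = 7.13e-17, and 0.181 with an estimated correlation). Dark and sugar starvation had 1.08 with 6 of 10 higher (adjusted over the list alone 7, with the block 10; adjusted p = 2.52e-05, and 0.175 with an estimated correlation). The cytosolic ribosome and nucleolus list had -0.84 with 5 of 25 lower (adjusted over the list alone 8, with the block 24; adjusted p = 2.8e-07, and 0.401 with an estimated correlation). Photosynthesis had -0.67 with 1 of 31 lower (adjusted over the list alone 1, with the block 22 and 1 higher; adjusted p = 0.000121, and 0.558 with an estimated correlation) and chlorophyll -0.79 with 1 of 11 (adjusted over the list alone 3, with the block 10; adjusted p = 0.00236, and 0.181 with an estimated correlation). Autophagy had 0.50 with 0 of 23 called by limma (adjusted over the list alone 0, with the block 15; adjusted p = 0.00236, and 0.221 with an estimated correlation). XTH genes had 1.06 with 7 of 17 higher and 2 lower (adjusted over the list alone 9 and 3, with the block 9 and 4; adjusted p = 0.00419, and 0.221 with an estimated correlation), and immune response genes 0.73 with 7 of 20 higher and 1 lower (adjusted over the list alone 10 and 2, with the block 12 and 4; adjusted p = 0.00652, and 0.181 with an estimated correlation). Aux/IAA and GH3 genes had 0.86 with 5 of 16 higher and 3 lower (adjusted over the list alone 7 and 3, with the block 9 and 3; adjusted p = 0.0112, and 0.263 with an estimated correlation).

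The last 4 of the 14 were lost in some fits, and 3 lists not called passed in some. Seed storage (0.0931) passed without Col-0 rapamycin 1 (0.031), RiD mock 2 (0.000135), RiD brassinolide 1 (0.0434) or RiD brassinolide 2 (0.043), cellulose genes (0.15) without RiD mock 2 (0.0457) or RiD rapamycin 1 (0.0313), and xylem markers (0.15) without RiD mock 2 (0.0457). With an estimated correlation these 3 were at 0.608, 0.608 and 0.596. Gibberellin metabolism and signalling had a median difference of 0.37 with 5 of 15 higher (adjusted over the list alone 5 and 1 lower, with the block 6 and 2; adjusted p = 0.023, with the block 0.0933, and 0.181 with an estimated correlation). Root endodermis and stele markers had 0.76 with 3 of 6 higher (adjusted over the list alone 3, with the block 3 and 1 lower; adjusted p = 0.0208, with the block 0.0991, and 0.193 with an estimated correlation). Cell division had -0.62 with 1 of 21 lower (adjusted over the list alone 4 lower and 2 higher, with the block 11 and 2; adjusted p = 0.0414, and 0.21 with an estimated correlation). It was lost without Col-0 mock 1 (0.0922), Col-0 rapamycin 1 (0.0737), RiD mock 1 (0.0627), RiD rapamycin 1 (0.0531) or RiD rapamycin 2 (0.0502). Root hair and root epidermis markers had -3.20 with 5 of 10 lower and 1 higher (adjusted over the list alone 6 and 2, with the block 6 and 2; adjusted p = 0.0335, with the block 0.158, and 0.221 with an estimated correlation). They were lost without Col-0 mock 1 (0.0669), Col-0 rapamycin 1 (0.0504) or RiD rapamycin 1 (0.0701). The count of 2341 loci was 1286 without Col-0 mock 1, 1490 without Col-0 mock 2, 1519 without Col-0 rapamycin 1, 1299 without Col-0 rapamycin 2, 1371 without RiD mock 1, 1529 without RiD mock 2, 1498 without RiD rapamycin 1 and 1225 without RiD rapamycin 2, and 7893 with the block. The members called of the ribosome list were 1 to 3 without any 1 library, and those of starvation 3 without Col-0 mock 1, Col-0 mock 2, Col-0 rapamycin 2, RiD mock 1 or RiD rapamycin 2. XTH genes had 5 without Col-0 rapamycin 2, and Aux/IAA and GH3 genes 5 without Col-0 mock 2, Col-0 rapamycin 1, RiD mock 1 or RiD rapamycin 2. Gibberellin genes had 2 without Col-0 mock 1 or RiD rapamycin 2 and 3 without Col-0 mock 2, Col-0 rapamycin 1, RiD mock 1 or RiD rapamycin 1. Photosynthesis had 0 without Col-0 mock 2, Col-0 rapamycin 2 or RiD rapamycin 2 and 2 without RiD rapamycin 1, and chlorophyll had 0 except without RiD rapamycin 1. Cell division had 0 without Col-0 mock 2, Col-0 rapamycin 1, RiD mock 1, RiD rapamycin 2, RiD brassinolide 1 or RiD brassinolide 2, and root hair markers had 3 without Col-0 mock 1, Col-0 rapamycin 1, Col-0 rapamycin 2 or RiD rapamycin 2.

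Brassinolide in RiD changed some of the same genes as rapamycin, among them DWF4, CPD and SAUR9. DWF4 fell from 2903 ± 0.215 to 1219 normalized counts, 2.38-fold (log2 change -1.25, SE 0.16, adjusted p = 0.00356), and CPD from 17039 ± 1794 to 7249 ± 1196, 2.36-fold (adjusted p = 0.00488, and 0.05 without RiD brassinolide 1, where the call was lost). SAUR9 rose from 28.6 ± 0.272 to 569 ± 52.5, 19.2-fold (adjusted p = 0.000226). RD22, a dehydration-responsive gene, rose from 4323 ± 243 to 14294 ± 231, 3.31-fold (adjusted p = 0.000397), and DIN2 from 6952 ± 317 to 32873 ± 6273, 4.69-fold (adjusted p = 0.00242). In RiD brassinolide against RiD mock 1575 loci were called, 1079 higher and 496 lower, and 6424 with the block, which held 1570 of them. The count was 696 without RiD mock 1, 744 without RiD mock 2, 473 without RiD brassinolide 1 and 884 without RiD brassinolide 2. With the block it was 3857 without RiD mock 1 and 3264 without RiD brassinolide 1.

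Of the BR biosynthesis list 4 of 10 fell with brassinolide (adjusted over the list alone 5, with the block 7), with a median of -0.69 (adjusted p = 6.53e-05, and 0.142 with an estimated correlation). Of these 2 were called without RiD mock 2 and 1 without RiD brassinolide 1. BR6OX2 fell from 7464 ± 651 to 2937 (adjusted p = 0.0091), a call lost without RiD mock 2 (0.0616) or RiD brassinolide 1 (0.0819). BAS1 rose to 890.4 ± 129.8 (adjusted p = 0.00733, and 0.0531 without RiD brassinolide 2). Of the SAUR genes 13 of 20 rose (adjusted over the list alone 19), with a median of 2.00 (adjusted p = 1.54e-15, and 0.259 with an estimated correlation). In that list 4 were called without RiD mock 2 or RiD brassinolide 1 and 5 without RiD brassinolide 2. SAUR16 rose 6.05-fold, SAUR62 4.07-fold and SAUR10 20.1-fold. Aux/IAA and GH3 genes had 3 of 16 higher (adjusted over the list alone 5, with the block 8), with a median of 0.42 (adjusted p = 0.00663, and 0.259 with an estimated correlation), among them IAA6, 7.45-fold, and GH3.2, 3.54-fold. The xyloglucan endotransglucosylases had 4 of 17 higher and 2 lower (adjusted over the list alone 7 and 2, with the block 9 and 3), with a median of 0.42 and an adjusted p of 0.00696, which was 0.259 with an estimated correlation and 0.0667 without RiD brassinolide 2. XTH23 rose 3.25-fold. In all fits but those without Col-0 mock 1, Col-0 mock 2 or RiD rapamycin 2, 1 to 3 of these XTH genes were called. Abscisic acid and drought response had 3 of 12 higher (adjusted over the list alone 4, with the block 6), with a median of 0.76, or 0.66 with genes at 0 set to the floor (adjusted p = 0.000418, and 0.259 with an estimated correlation), and 1 without RiD mock 2 or RiD brassinolide 1, which was RD22.

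Dark and sugar starvation had 6 of 10 higher with brassinolide (adjusted over the list alone 7, with the block 10), with a median of 0.73 (adjusted p = 9.3e-06, and 0.142 with an estimated correlation), and 3 without RiD mock 2 and 1 without RiD mock 1, RiD brassinolide 1 or RiD brassinolide 2. The cytosolic ribosome and nucleolus list had 1 of 25 lower (adjusted over the list alone 1, with the block 24), with a median of -0.50 (adjusted p = 2.3e-06, and 0.365 with an estimated correlation), and 0 in 6 of the fits that left out a library, those of Col-0 mock, RiD mock and RiD brassinolide. Chlorophyll synthesis had 0 of 11 called by limma (adjusted over the list alone 0, with the block 7 lower), with a median of -0.32 and an adjusted p of 0.0272, which was 0.259 with an estimated correlation, 0.126 without RiD mock 1 and 0.0642 without RiD brassinolide 2. Autophagy had 0 of 23 called by limma (adjusted over the list alone 0, with the block 11 higher), with a median of 0.28 (adjusted p = 0.00781, and 0.259 with an estimated correlation). Root hair and root epidermis markers had 6 of 10 lower and 1 higher, the same adjusted over the list alone (with the block 6 and 2), with a median of -2.70, or -2.47 with genes at 0 set to the floor (adjusted p = 0.000746, and 0.197 with an estimated correlation); 3 were lower without RiD mock 1 or RiD brassinolide 1. PRP3, of root hair walls, fell from 63.1 ± 14.7 to 1.54 ± 2.18 and EXPA7 from 35.6 ± 6.23 to 0, at least 11.3-fold. Seed storage and embryo remnants had 1 of 12 higher (adjusted over the list alone 4, with the block 1), with a median of 2.21. The adjusted p was 0.00473, which was 0.365 with an estimated correlation and 0.135 without RiD mock 1. The call was 0 without RiD mock 1 or RiD brassinolide 1, 4 without RiD mock 2 and 2 without RiD brassinolide 2.

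A further 5 lists were not called with brassinolide, yet passed in other fits, the first 4 of them with the block. With an estimated correlation none passed, at an adjusted p of 0.259 to 0.745 without the block and 0.404 to 0.648 with it. Immune response genes had 7 of 20 higher and 1 lower (adjusted over the list alone 7 and 3, with the block 9 and 2), with a median of 0.21 and an adjusted p of 0.0533, which was 0.032 with the block and 0.0264 without RiD mock 2. WRKY70 rose from 136 ± 23.4 to 642 ± 79.4. Xenobiotic response had 3 of 10 lower (adjusted over the list alone 3, with the block 5 lower and 1 higher), with a median of -0.21 and an adjusted p of 0.051, which was 0.0162 with the block, 0.0127 without RiD mock 2 and 0.00256 without RiD brassinolide 1. UGT74E2 fell from 1097 ± 40.3 to 178 ± 33.3. Xylem and secondary wall markers had 0 of 8 called by limma (with the block 4 higher), with a median of 0.47 and an adjusted p of 0.0533, which was 0.032 with the block, 0.00952 without RiD mock 2 and 0.00256 without RiD brassinolide 1. Nuclear photosynthesis genes had 0 of 31 called (with the block 5 lower and 1 higher), with a median of -0.14 and an adjusted p of 0.104, which was 0.0133 with the block. This list passed also without RiD mock 2 or RiD brassinolide 1, but its direction turned without RiD mock 1. Root endodermis and stele markers had 2 of 6 higher (adjusted over the list alone 3, with the block 3 and 1 lower), with a median of 0.33 and an adjusted p of 0.05, which was 0.0457 without RiD mock 1, 0.0449 without RiD mock 2 and 0.0289 without RiD brassinolide 1. GPAT5 rose from 2.74 ± 1.61 to 96.8 ± 12.3. Immune response calls were 4, 5, 2 and 5 without RiD mock 1, RiD mock 2, RiD brassinolide 1 and RiD brassinolide 2, and endodermis had 1 without RiD brassinolide 1.

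Other lists were not called with brassinolide. BR inactivation had a median of 0.32 (adjusted p = 0.0933), BR signalling components 0.10 (0.293), expansins 0.25 (0.111), cellulose 0.00 (0.831), gibberellin genes 0.03 (0.104), dark growth regulators 0.01 (0.675), flavonoid genes 0.09 (0.85), cell division genes 0.06 (0.111) and stomatal markers 0.02 (0.278, and 0.0496 without RiD brassinolide 1). BR-responsive growth regulators had a median of 0.23 and a mean of -0.02 (0.111). PRE3 fell by 5.38 on the log2 scale, to 1.43 ± 0.158, EXPB3 rose from 56.2 ± 8.15 to 197 ± 15.5, GA2OX8 rose from 2.49 ± 0.128 to 107 ± 9.15, and TMM rose from 113 ± 7.1 to 405 ± 4.78. The mitotic cyclin CYCB1;3 rose from 30.1 ± 6.08 to 118 ± 14.5 (adjusted p = 0.00599, and 0.0635 without RiD brassinolide 1). Outside the lists BCB rose 178-fold to 6291 ± 2308, JRG21 (AT3G55970), a jasmonate-regulated gene, rose from 11.2 ± 6.75 to 789.9 ± 45.6, and AGP30 (AT2G33790), of a root arabinogalactan protein, fell from 138 ± 15.0 to 1.16 ± 1.64. Apart from CPD, BR6OX2, BAS1 and CYCB1;3, each gene given with a rise or fall with brassinolide was called in every fit that left out 1 library. Other called loci of the naming rule, not described here, lost the call in some of these fits.

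**Figure D3:**
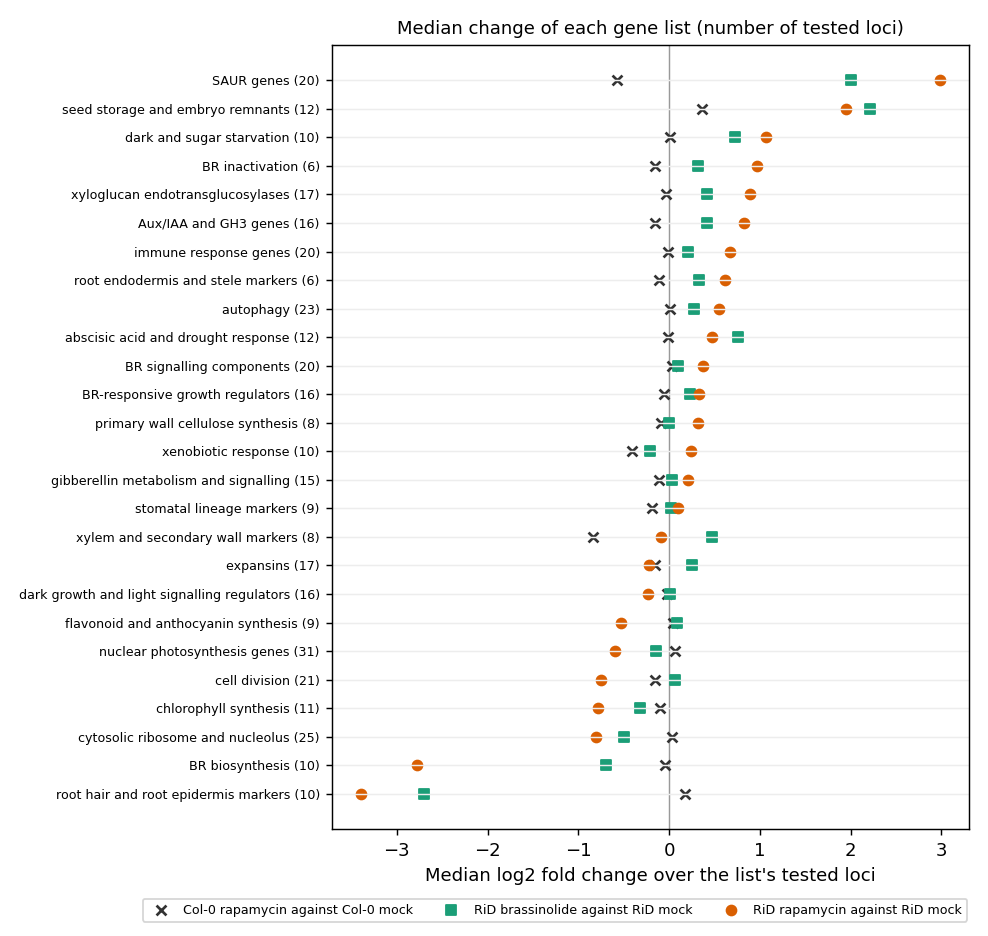
Median log2 fold change of each of 26 gene lists, with its number of tested loci in brackets, for RiD rapamycin against RiD mock (circles), RiD brassinolide against RiD mock (squares) and Col-0 rapamycin against Col-0 mock (crosses). SAUR genes had medians of 2.98, 2.00 and -0.57 and BR biosynthesis -2.78, -0.69 and -0.04; with another scaling the brassinolide medians of cellulose, dark growth and stomatal genes, 0.00 to 0.02, changed sign.

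The responses of RiD to rapamycin and to brassinolide were correlated, and most loci called in each had the same direction. Across the tested loci, which are not independent replicates, the log2 changes correlated at r = 0.81 and rho = 0.76. Simulated unchanged groups gave 0.50 (range 0.47 to 0.53) and 0.45, with the RiD mock libraries redrawn as well and shared by both comparisons. The covariance was 0.789, against 0.065 simulated. In both comparisons 1464 loci were called in the same direction, 1016 higher and 448 lower, where independent lists would share 180, and 3 in opposite directions, where independent lists would share 166. With the block 5633 were called in the same direction and 53 in opposite ones. Within each number r was 0.77, and it was 0.74 with brassinolide set against Col-0 mock so that no library was shared. The response of Col-0 to rapamycin correlated with that of RiD to brassinolide at r = -0.01. The 3 loci called in opposite directions, chosen after their values were seen, were CYP710A2 (AT2G34490), of stigmasterol synthesis, with means of 3.54 in RiD mock, 0 in RiD rapamycin and 37.1 in RiD brassinolide, AT2G37870 with log2 changes of -2.88 with rapamycin and 2.09 with brassinolide, and AT4G11211 with -1.86 and 0.94. The fall of CYP710A2 with rapamycin lay near the floor of 3 reads per library, which averaged 3.24 in RiD rapamycin. Its size therefore depends on the constant added before the logarithm.

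Set directly against brassinolide, rapamycin gave lower transcripts of 5 of 10 genes of the BR biosynthesis list. DWF4 was 48.0-fold lower in RiD rapamycin than in RiD brassinolide, with 24.5 ± 3.19 against 1219 normalized counts (log2 difference -5.58, SE 0.16, adjusted p = 3.72e-06), CPD 6.01-fold lower (adjusted p = 0.000327) and BR6OX2 130-fold lower (adjusted p = 4.86e-06). EXPA5 was 17.9-fold lower, with 27.4 ± 1.32 against 508 ± 30.8 (adjusted p = 2.72e-05). In this comparison 596 loci were called, 240 higher and 356 lower with rapamycin, and 4650 with the block, which held all 596. The share higher with rapamycin was 40.3%, and 54.5% with the block. The count was 167 without RiD rapamycin 1, 159 without RiD rapamycin 2, 127 without RiD brassinolide 1 and 113 without RiD brassinolide 2, and with the block it was 1972 without RiD rapamycin 2, 2783 without RiD brassinolide 1 and 2158 without RiD brassinolide 2. Of the 596, 169 were called in the same direction with each treatment and lay further from mock with rapamycin, and 8 lay further with brassinolide. Another 375 were called with rapamycin alone, 21 with brassinolide alone, 3 in opposite directions and 20 with neither.

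BR biosynthesis had 5 of 10 lower in rapamycin than in brassinolide (6 lower and 1 higher when adjusted over the list alone, and with the block), with a median of -1.87 (adjusted p = 1.26e-10), and held with an estimated correlation (adjusted p = 0.0111, and 0.158 with the block as well). Its members BR6OX1, with 1.46 ± 0.0979 against 228 ± 18.6, and CYP90D1 (AT3G13730), with 0.696 ± 0.984 against 80.1 ± 33.1, were lower also in every fit that left out 1 library. So were PIZ, with 86.3 ± 21.5 against 538 ± 2.07, BEH2, with 549 ± 84.2 against 3033 ± 863, and IAA29, by 1.89 on the log2 scale from 375 ± 19.8. Most called loci of the naming rule, however, lost the call of this comparison in some of these fits. Cell division had a median of -0.82 (adjusted p = 3.15e-11) and held with an estimated correlation (adjusted p = 0.0111, and 0.158 with the block as well). Of its 21 genes 2 were lower, 11 when adjusted over the list alone and 16 with the block. These 2 were CYCA1;1 (AT1G44110), with 19.8 ± 2.35 against 54.2 ± 3.47, and MCM4, by 0.87 on the log2 scale from 185 ± 8.32. Neither was called in 9 of the 10 fits that left out a library, and 1 was without Col-0 rapamycin 2. MYB55 was lower with rapamycin, with 4.76 ± 0.833 against 710 ± 276, as was ACS11, with 0.695 ± 0.984 against 236 ± 17.7, and AT5G46890 was higher, with 23.4 ± 3.63 against 1.43 ± 0.158.

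Lists higher in rapamycin than in brassinolide and called by camera without any single library were the SAUR genes, with a median of 1.02 (adjusted p = 5.8e-08, and 0.229 with an estimated correlation), xenobiotic response with 0.60 (adjusted p = 0.00183, and 0.363 with an estimated correlation), dark and sugar starvation with 0.36 (adjusted p = 0.00233, and 0.226 with an estimated correlation) and immune response genes with 0.40, or 0.45 with genes at 0 set to the floor (adjusted p = 0.00248, and 0.157 with an estimated correlation). Lower in that sense were chlorophyll synthesis with -0.51 (adjusted p = 0.000263, and 0.115 with an estimated correlation) and abscisic acid and drought response with -0.49 (adjusted p = 0.00119, and 0.229 with an estimated correlation). Of these 6 lists 1 of 20 SAUR genes, 2 of 10, 0 of 10 and 1 of 20 were higher and 0 of 11 and 2 of 12 lower, against 7, 4, 1, 4, 3 and 3 when adjusted over the list alone and 8, 8, 8, 9, 7 and 4 with the block, where 1 xenobiotic response gene was also lower. Without any 1 of the RiD rapamycin and RiD brassinolide libraries 0 or 1 member was called of SAUR, xenobiotic, immune and abscisic acid genes. SAUR genes had 2 without RiD mock 1 or RiD mock 2. Without any 1 of the other 6 libraries xenobiotic response had 0 or 1, and immune genes had 0 without RiD mock 1, RiD mock 2, Col-0 rapamycin 1 or Col-0 rapamycin 2. Starvation had 1 without Col-0 rapamycin 1 or Col-0 rapamycin 2.

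The other 10 called lists were lost without some library. Photosynthesis, with a median of -0.40 (adjusted p = 5.33e-06, and 0.408 with an estimated correlation), and ribosome, with -0.31 (0.00014, and 0.431), were lost without RiD rapamycin 2 (0.0811 and 0.131). Xylem markers with -0.57 (0.00183, and 0.229) and expansins with -0.13 (0.00918, and 0.229) were lost without RiD brassinolide 2 (0.0947 and 0.064). Autophagy with 0.28 (0.00581, and 0.229) was lost without RiD rapamycin 1 (0.0594) or RiD brassinolide 2 (0.064), and flavonoid genes with -0.80 (0.0192, and 0.229) without the same libraries (0.0992 and 0.11). Cellulose genes with 0.35 (0.0348, and 0.46) were lost without RiD rapamycin 2 (0.541) or RiD brassinolide 1 (0.268), and root hair markers with 0.79, or 0.18 with genes at 0 set to the floor (0.0348, and 0.229), without the same 2 (0.179 and 0.157). Endodermis markers with 0.29 (0.0393, with the block 0.104, and 0.229) were lost without RiD rapamycin 2 (0.177), RiD brassinolide 1 (0.1) or RiD brassinolide 2 (0.0601). XTH genes with 0.34 (0.0393, and 0.338) were lost without Col-0 mock 1 (0.0529), Col-0 mock 2 (0.0528), Col-0 rapamycin 1 (0.0594), Col-0 rapamycin 2 (0.0597), RiD rapamycin 2 (0.106) or RiD brassinolide 1 (0.122). BR inactivation with 0.77 (0.0509) and dark growth regulators with -0.23 (0.0558) were called with the block (0.0361 and 0.0117), though not with an estimated correlation (0.229 each, and with the block as well 0.343 and 0.342). Without 1 library BR inactivation passed at 0.039 to 0.0481, those left out being Col-0 mock 1, Col-0 mock 2, Col-0 rapamycin 1, Col-0 rapamycin 2, RiD mock 1 and RiD mock 2. Dark growth regulators passed at 0.0212 to 0.0474 without Col-0 mock 1, Col-0 mock 2, RiD mock 1, RiD mock 2, RiD rapamycin 2 or RiD brassinolide 1.

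Without rapamycin or brassinolide, no locus was called between the lines. The light-harvesting gene LHCB1.1 (AT1G29920) averaged 412 normalized counts in Col-0 mock and 2350 ± 1033 in RiD mock, a log2 difference of 2.54 (SE 0.51, adjusted p = 0.921), and WRKY70 79.2 and 136 ± 23.4. CPD averaged 15715 ± 1661 in Col-0 mock and 17039 ± 1794 in RiD mock. By limma the count was 0, with 695 loci at an unadjusted p under 0.05 and a lowest adjusted p of 0.102, that of BAK1. It was 1 without Col-0 rapamycin 1, Col-0 rapamycin 2 or RiD mock 1 and 2 without RiD mock 2. With the block 83 were called, 53 higher and 30 lower in RiD, among them LHCB1.1 (adjusted p = 3.88e-08), LHCB2.1 with 1.06 (0.000313), EXPA8 with 0.50 (0.0391), WRKY70 with 0.76 (0.0323) and BEE1 with -0.62 (0.034). The block count was 25 without Col-0 mock 1, 35 without Col-0 mock 2, 328 without Col-0 rapamycin 1, 336 without Col-0 rapamycin 2, 41 without RiD mock 2 and 54 without RiD brassinolide 1. By camera 9 lists were called, each with 0 members called by limma (with the block 2 BR signalling components, 2 BR-responsive growth regulators, 1 Aux/IAA or GH3 gene and 1 expansin), none with an estimated correlation and each lost without some library. SAUR genes had a median of -0.40 (adjusted p = 2.17e-05, and 0.451 with an estimated correlation), lost without Col-0 mock 1 (0.0664) or RiD mock 2 (0.51). Seed storage had -1.06 (0.00062, and 0.446), lost without Col-0 mock 2 (0.104) or RiD mock 1 (0.777), where its direction turned. Aux/IAA and GH3 genes had -0.20 (0.000399, and 0.426), lost without Col-0 mock 1 (0.071) or RiD mock 2 (0.207), and ribosome genes -0.18 (0.00215, and 0.644), lost without the same libraries (0.532 and 0.611), with the direction turned without RiD mock 2. XTH genes had -0.15 (0.0246), expansins -0.13 (0.0346), gibberellin genes -0.13 (0.0407), BR-responsive growth regulators -0.08 (0.0407) and BR signalling components 0.10 (0.0494), and without RiD mock 2 these were 0.611, 0.4, 0.237, 0.477 and 0.975. XTH genes were lost also without Col-0 mock 1 (0.0664) or Col-0 mock 2 (0.157), expansins without these (0.0808 and 0.158) or RiD mock 1 (0.057), and gibberellin genes without these 3 (0.0774, 0.227 and 0.121), RiD rapamycin 1 or RiD rapamycin 2 (0.0534 each). BR-responsive growth regulators were lost without any library but RiD mock 1, and BR signalling components without any but Col-0 mock 2 and RiD mock 1.

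Other lists passed between RiD mock and Col-0 mock in some fits. With the block these were photosynthesis (0.00341), chlorophyll (0.0128), xenobiotic response (0.00733) and autophagy (0.0224), all higher in RiD. With an estimated correlation as well as the block they were 0.73, 0.537, 0.537 and 0.537, and without the block no list passed with an estimated correlation. Photosynthesis, with a median of 0.09 and an adjusted p of 0.0877, passed also without Col-0 mock 1 (0.00225) or RiD mock 2 (3.36e-07), but its direction turned without Col-0 mock 2 (0.98) or RiD mock 1 (0.183). Without Col-0 mock 1 xenobiotic response (0.00612), autophagy (0.0417) and root endodermis markers (0.0361) passed, the last lower in RiD. Without RiD mock 2 chlorophyll and xenobiotic response passed as higher and xylem markers as lower. The direction of the xylem markers turned without Col-0 mock 2 or RiD mock 1. The fits that left out a mock library set unequal numbers against each other.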

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

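The tests in this part were planned, and none was chosen after its result was seen. Each result here was singled out because a test of the difference between the effects of rapamycin in RiD and in Col-0 passed its threshold. That test called 2341 loci. Among the loci named by the rule, the log2 effect in RiD minus that in Col-0 was -8.21 for BR6OX2, -9.51 for AT5G57785, -9.36 for AT5G01740, -8.69 for AT5G22580, -8.15 for ACS11 and -7.78 for MYB55. It was 9.90 for CYP78A10, 9.47 for PELPK1, 9.36 for NRT2.1, 9.19 for PELPK2, 8.93 for LAC5 and 8.77 for ABCG6. Apart from BR6OX2, PELPK1 and AT5G22580, each of these loci had a group at or near the floor of 3 reads per library, so its value depends on the constant added before the logarithm and is no measure of fold. For AT5G57785, at 0 in RiD rapamycin, the fall from RiD mock was at least 236-fold, and for NRT2.1, at 0 in RiD mock, the rise was at least 89.4-fold.

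Lists were singled out in the same way by camera, on the difference of the effects. Their median differences were -2.69 for BR biosynthesis, 3.68 for SAUR genes, 0.86 for Aux/IAA and GH3 genes, 1.06 for xyloglucan endotransglucosylases, 0.37 for gibberellin metabolism and signalling and 0.73 for immune response genes. They were -0.67 for nuclear photosynthesis genes, -0.79 for chlorophyll synthesis, -0.84 for cytosolic ribosome and nucleolus, 0.50 for autophagy, 1.08 for dark and sugar starvation, -0.62 for cell division, -3.20 for root hair and root epidermis markers and 0.76 for root endodermis and stele markers. Of these 14, BR biosynthesis alone passed with an estimated correlation, though not with the block as well. The gibberellin, root hair and root endodermis lists were not called with the block.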

How the results depend on the processing

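The edgeR tests, unsummed transcripts and block fits without a library were chosen after seeing the data. Counts of called loci stayed within 1.5 times the reported count with either other pseudocount, either filter, TMM or quantile scaling and a 2-fold limit, in all 6 comparisons. With the replicate number as a block they were 43 for Col-0 rapamycin against mock (0 reported), 11215 for RiD rapamycin against mock (5120), 6424 for RiD brassinolide against mock (1575), 4650 for RiD rapamycin against brassinolide (596), 7893 for the difference of the rapamycin effects (2341) and 83 for RiD mock against Col-0 mock (0). BAK1 and BRI1, at 1.33 and 1.22 in RiD mock against Col-0 mock, passed the threshold with the block alone. Over the fits without the block that left out a library BRI1 ran from 0.86 to 1.57, a range that includes the shift between the numbers. The block removes the shift between the numbers from the residual spread. It changed the calls of lists as given with each comparison and no others.

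At an adjusted p under 0.01 the counts were 2620, 607 and 165 in the RiD comparisons in the order above and 863 for the difference of effects. With only the libraries compared, and so fewer residual degrees of freedom, the RiD counts were 2548, 535 and 61. By edgeR without the block they were 3840, 986 and 181, and with it 11324, 6714 and 5322. With transcripts not summed to loci they were 943 for brassinolide, 296 for rapamycin against brassinolide, 1423 for the difference of effects, 2 for Col-0 rapamycin and 1 for RiD mock against Col-0 mock, where limma without a trend also called 1. For counts not explained by a stricter threshold, the block or fewer libraries, the cause was not tested. Leaving out 1 library, which assumes that a lone library varies like the other groups, gave 0 to 1 loci for Col-0 rapamycin, 2945 to 4668 for RiD rapamycin, 473 to 1320 for RiD brassinolide, 113 to 429 for rapamycin against brassinolide, 1225 to 1890 for the difference of effects and 0 to 2 for RiD mock against Col-0 mock. With the block these ranges were 5 to 405, 8011 to 12068, 3264 to 7537, 1972 to 5756, 5673 to 8289 and 25 to 336.

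With an estimated correlation camera called 0 lists in Col-0 rapamycin (6 reported), 0 in RiD rapamycin (12), 0 in RiD brassinolide (11), 2 in rapamycin against brassinolide (18), 1 for the difference of effects (14) and 0 in RiD mock against Col-0 mock (9). By fry, which tests a list against no change and not against other loci, the counts in this order were 0, 17, 14, 8, 14 and 0. At an adjusted p under 0.01 there were 9 for the difference of effects and 4 for RiD mock against Col-0 mock, where a pseudocount of 10 gave 5. Leaving out 1 library gave 3 to 10 lists in Col-0 rapamycin and 4 to 7 in RiD mock against Col-0 mock. The correlation of the rapamycin and brassinolide responses, 0.81, was 0.77 with a pseudocount of 0.1, 0.84 with 10, 0.84 with a value of at least 10 in 2 libraries, 0.88 for loci called in either comparison, 0.85 for loci above the median mean and 0.74 with brassinolide against Col-0 mock, and 0.74 to 0.84 with 1 library left out. The cause was not tested.

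Of 294 pairs of a named locus and a comparison, all called except BAK1 and BRI1 in RiD mock against Col-0 mock, 0 changed sign in any setting and 120 of the called pairs lost the call in at least 1. Depth limits loci of few reads, since 3 reads were 2.19 to 4.18 normalized counts. Other settings meant for raw counts (median-ratio size factors or library size alone in place of TMM, other filters on counts, DESeq2 and voom) were not run, as the table held normalized values, and the edgeR tests on recovered reads of the 6 RiD libraries were the count tests made.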

Other observations

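Gene families formed from symbol stems were tested only after the results were seen, and the depth test below was likewise chosen after its result was seen, in place of an earlier version that could not decide. Of 202 families, the WRKY transcription factors had 25 of 61 members higher in RiD rapamycin than in RiD mock and 0 lower, with a median log2 change of 0.70 (adjusted p by camera 2.28e-05, and 0.663 with an estimated correlation), and 13 higher and 0 lower in RiD brassinolide, with a median of 0.41 (4.27e-05, and 0.45). With the block these counts were 39 higher and 7 lower with rapamycin and 31 higher and 3 lower with brassinolide. The GPAT acyltransferases, of cutin and suberin synthesis, had 6 of 9 higher with rapamycin, with a median of 3.11 (8.66e-05, and 0.663), and 5 with brassinolide (8 with the block), with a median of 2.22 (2.93e-07, and 0.45). The WAKL kinases had 6 of 8 higher with rapamycin, with a median of 1.62 (0.00663, and 0.663).

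The MCM helicase genes had 5 of 9 lower with rapamycin, with a median of -1.03 (adjusted p by camera 0.0212, and 0.799 with an estimated correlation), and 0 called by limma with brassinolide, with a median of -0.22 (0.408, and 0.992). In rapamycin against brassinolide their median was -0.71 (0.0112, and 0.931), with 1 lower and 6 with the block. The B-type cyclins had 4 of 10 higher with brassinolide, with a median of 0.88 (0.00554, and 0.45), and 2 with rapamycin, with a median of -0.07 (0.772, and 0.922). In rapamycin against brassinolide their median was -0.71 (0.00274, and 0.895), with 0 called by limma and 2 lower with the block. The PRMT methyltransferase genes had 6 of 8 lower with rapamycin, with a median of -0.77 (0.00554, and 0.663), and 0 called by limma with brassinolide (5 lower with the block), with a median of -0.45 (0.00718, and 0.45). No family call held with an estimated correlation.

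Of the 1575 loci called with brassinolide, 1176, or 74.7%, lay further from mock in the same direction with rapamycin. With TMM or quantile scaling the lower share was 73.8%, which argues against scaling of the libraries as the cause. The share was 70.8% in the lower of the 2 numbers, so that a single set of libraries could not account for it as a whole. It was 77% for loci chosen against Col-0 mock. Mock values cancel when rapamycin is set against brassinolide and enter only through the choice of loci and the direction. The 77% therefore decides nothing about chance values of the RiD mock libraries. A larger response of the RiD line to 100 nM rapamycin than to 100 nM brassinolide is a hypothesis from the same data, and with a single dose of each compound the relation to dose was not tested.

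In rapamycin against brassinolide the cell division list had a median of -0.82, with 2 of 21 genes lower, neither of them called in 9 of the 10 fits that left out a library, and its test with an estimated correlation (adjusted p = 0.0111) was lost with the block (0.158). The median residual after scaling of the brassinolide response, -0.83, lay at percentile 0 of 10000 random lists and was negative in 21 of 21 genes. The random lists were drawn locus by locus, without the co-expression of a list. This therefore argues only weakly against a uniformly larger response to rapamycin. Scaling of the libraries was argued against by a median of -0.76 in the nearer of the 2 scalings. Inhibition of the TOR kinase by rapamycin may contribute, as the residual of the ribosome list, -0.19, lay at percentile 0.03. That list was lower also with brassinolide alone, with a median of -0.50, so its fall by itself is no mark of rapamycin. However, 18 of the 26 lists lay outside the middle range of random lists. The test against random lists thus discriminates weakly, for a uniformly larger response as for TOR inhibition. In Col-0 the medians with rapamycin were -0.15 for cell division (adjusted p = 0.267) and 0.03 for the ribosome list (adjusted p = 0.793), so the ribosome list gave no sign of such inhibition there.

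Between libraries numbered 1 and 2, 10426 of 23285 loci differed, 4960 higher and 5466 lower in number 2, and 685 at least 2-fold. Counting noise from a difference in depth was argued against as the whole cause, because the difference between the 2 libraries of a group correlated between groups at 0.74 or more among loci with a mean of at least 1000. That is the correlation that showed the pattern, taken over more abundant loci, so it is no separate test. Transcript length and GC content together explained 41.4% of the variance of the shift, with rho 0.64 for length and 0.22 for GC content, and could be part of it. What the number stands for is not given in the sources used here, and no biological explanation was tested.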
